A study of Homo sapiens with 4 samples.

How the data were processed

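Poly(A)-selected RNA from RD cells was sequenced in 4 libraries, 2 from parental cells and 2 from vincristine-resistant cells. Groups and replicate numbers were taken from the sample titles, and the table columns were matched to samples through the column names given in the labels. Per the submitters' processing notes, the tools were bcl2fastq 2.17, STAR 2.5.2b, featureCounts from Subread 1.5.2 and DESeq2, with the genome build GRCh38. The gene annotation and the strand setting are not given in the sources used here.

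The deposited table has 18375 genes with Ensembl identifiers, of which 17828 carry a symbol. Each library's column is a signal of normalized counts, which the authors made by dividing gene counts by one size factor per library, as the values themselves show. In every column 100% of the values were whole multiples of one step within a tolerance of 0.01, so whole reads were recovered exactly. The size factors were 1.03 and 1.01 for the parental and 0.924 and 1.05 for the resistant libraries. The log2 column holds fold changes of resistant over parental cells computed by the authors, per the file headers. The p-value columns deposited by the authors hold raw and adjusted values, and recomputing a Benjamini-Hochberg adjustment over the genes of the table gave the deposited values to within 1.2e-15. The smallest mean normalized count of a gene was 9.98, so weakly expressed genes are not covered. The recovered reads per library ranged from 58861281 to 67690557 over these genes, and reads of other genes are not part of that total. The 20 most abundant genes took 6.87 to 7.11% of the reads. Intervals for genes with few reads are exact 95% binomial intervals of the read ratio and cover counting error only, since polymerase chain reaction copies are not independent molecules.

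Each planned test was fixed in writing for either raw counts or normalized values before the data were examined, and the form for normalized values applied. Genes with a value of at least 10 in at least 2 libraries were kept, which left 18330. The log2 of the value plus a pseudocount of 1 was fitted with limma 3.58.1 (lmFit, and eBayes with an intensity trend) on group alone, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are on this log2 scale with pseudocount, which can understate the change of weakly expressed genes but does not always do so. For SERTM2 the fold was 72.8 against a read ratio of 146, and for DCX 216 against 214. The common dispersion between replicates, estimated by edgeR 4.0.16 on the recovered reads, was 0.000566, a coefficient of variation of 2.38%. Software ran in R 4.3.3, with DESeq2 1.42.0 on the recovered reads as an alternative, and figures were drawn with matplotlib.

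Gene lists were written down before the data were examined, 28 in all, covering the axis named in the title, vincristine's target and efflux, muscle lineage, proliferation, stress, metabolism and markers of other cell types. Each measured member was counted as higher, lower or not past the threshold, and each list with at least 5 measured members was tested with camera (limma, preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the 28 lists. Counts adjusted over the list alone equalled those adjusted over all genes in every list except the genes of the p21 axis and damage response (13 higher in place of 12) and the mitosis genes (5 lower in place of 4). Several genes stand in more than one list.

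The genes named in the text follow a rule fixed before the data were examined. It takes genes of the title and the drug, among them CDKN1A, MYC, MAP2K1, MAP2K2, BCL2L1 and ABCB1, then the 12 largest and 12 smallest log2 fold changes among called genes with an official symbol, a mean of at least 100 in the higher group and no overlap between groups, then up to 4 members of each list with the smallest adjusted p, and the most abundant member of each list of another cell type. Some genes that the rule takes are not reported here. Members named outside the rule are marked in the text as chosen after their values were seen, and their calls were repeated under every alternative setting. Exonic overlaps with other genes were counted for the genes of the rule alone. Beside the overlaps given with the results, BAALC, NQO1, KRT7 and MAP2K1 share 18.9, 18.4, 12.6 and 12.3% of their exonic bases with one gene on the opposite strand, and ZNF883 (46.6%) and PSMB9 (15.1%) with one on the same strand, so their counts are uncertain.

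Genes were placed with GENCODE 29 on GRCh38, which holds 17804 of the identifiers (96.9%), and GC content and length of the longest annotated transcript were available for 96.9% of the tested genes. The running median of log2 fold change over 21 consecutive genes was compared with 1000 shuffles of gene order. Segments of at least 30 genes were then found by circular binary segmentation of values limited to 1.5 in size, with splits kept when none of 1000 shuffles gave as large a statistic, and segments with a median of at least 0.25 in size were called shifted. The segmentation was added after the data were seen, and it was repeated on every other gene so that the genes left out could be tested. Earlier forms of it missed a block of genes planted in shuffled data, and it was rewritten until it found the block.

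The methods were tested on simulated data. Among 18211 simulated genes, limma recovered 57 of 100 planted changes of 1.2-fold and 85 of 100 planted changes of 2-fold, with 0 false calls, and edgeR recovered 58 and 85, also with 0 false calls. DESeq2 recovered fewer, 40 and 78, with 0 false calls. The simulated counts took their spread from these same replicates, and far fewer genes were changed than were called in the data. The 0 false calls therefore do not test whether the replicate spread is too narrow. Camera called 0 of 28 lists on simulated libraries with no change. The simulated genes were drawn independently, so this does not test false calls from correlation between genes. In the data that correlation was estimated at 0.488 for ribosomal protein genes. In a simulation of 17727 genes in shuffled order, the segmentation called 0 regions, and with a planted block of 100 genes shifted by -0.5 it called 1 region that held 98 of them. Finding the block is no independent test, since the segmentation was rewritten until it did so.

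Alternatives planned in advance were quantile normalization, scaling to the same total, no filter, a filter of 50, pseudocounts of 0.5 and 5, edgeR, DESeq2 and limma-voom on the recovered reads, leaving out each library, leaving out the 20 most abundant genes, the replicate number as a block, other windows, and for lists an estimated correlation and limma's fry. A fit without 1 library keeps 1 library in that group, so its p-values rest on the spread of the other group alone. Alternatives added after the data were seen were limma's treat test against 1.2-fold, a fixed dispersion of 0.01 in edgeR (a coefficient of variation of 10%), a correction of each library for GC content and length by splines, removal of the median shift of the 20 nearest neighbours, leaving out genes in shifted regions, and the segmentation on every other gene. The removal takes the neighbour median as known, so its p-values leave out the error of that median.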

Results

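RNA sequencing was used to measure gene expression in RD cells, an established line from a fusion-negative rhabdomyosarcoma, a childhood soft tissue tumour of the skeletal muscle lineage. The series holds 4 libraries, 2 from parental cells and 2 from vincristine-resistant cells. Vincristine is a vinca alkaloid that binds tubulin and blocks the mitotic spindle. The resistant cells were selected from a starting dose of 1 to 1.5 nM, which killed about 80 to 90% of the cells, by dose steps of 10 to 20% over 9 to 12 months, and their half-maximal inhibitory concentration rose at least 100-fold. The libraries held 67690557 and 65818879 recovered reads in parental cells and 58861281 and 67270948 in resistant cells, summed over the 18375 genes of the deposited table. The labels do not say whether replicates came from separate cultures or separate selections, so p-values measure only the spread between these libraries, which may be technical. The 2 libraries of each group differed by more than sampling noise, with a chi-square per gene of 1.61 in the parental pair and 4.04 in the resistant pair.

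The title of the study points to MEK, MYC, p21 and BCL-xL, and the first question was how the genes behind these names differed between resistant and parental cells. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 3396 ± 17.6 to 6276 ± 174 normalized counts (SD, n = 2 libraries in each group here and below), a log2 fold change of 0.89 (SE 0.04). MYC, a transcription factor of growth and ribosome synthesis genes, rose from 11509 ± 116 to 15716 ± 767, by 0.45 (SE 0.03) on the log2 scale. BCL2L1, the gene of the anti-apoptotic protein BCL-xL, was lower in resistant cells, at 5901 ± 32.4 against 10793 ± 132, a log2 fold change of -0.87 (SE 0.03). The MEK kinase genes were lower as well. MAP2K1 had 34529 ± 57.4 normalized counts against 37978 ± 610, a log2 fold change of -0.14 (SE 0.03), and MAP2K2 had 10883 ± 1.23 against 15407 ± 273, a log2 fold change of -0.50 (SE 0.03). Each of these genes passed the limma test with Benjamini-Hochberg adjustment, and the least certain was MAP2K1 (limma adjusted p = 7.00e-05). With a dispersion fixed at 0.01 in edgeR, an assumed spread between cultures chosen after seeing the data, MAP2K1 (edgeR adjusted p = 0.479) no longer passed, nor did it against 1.2-fold. ABCB1, the gene of the efflux pump P-glycoprotein, was not analysed here.

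**Figure D1:**
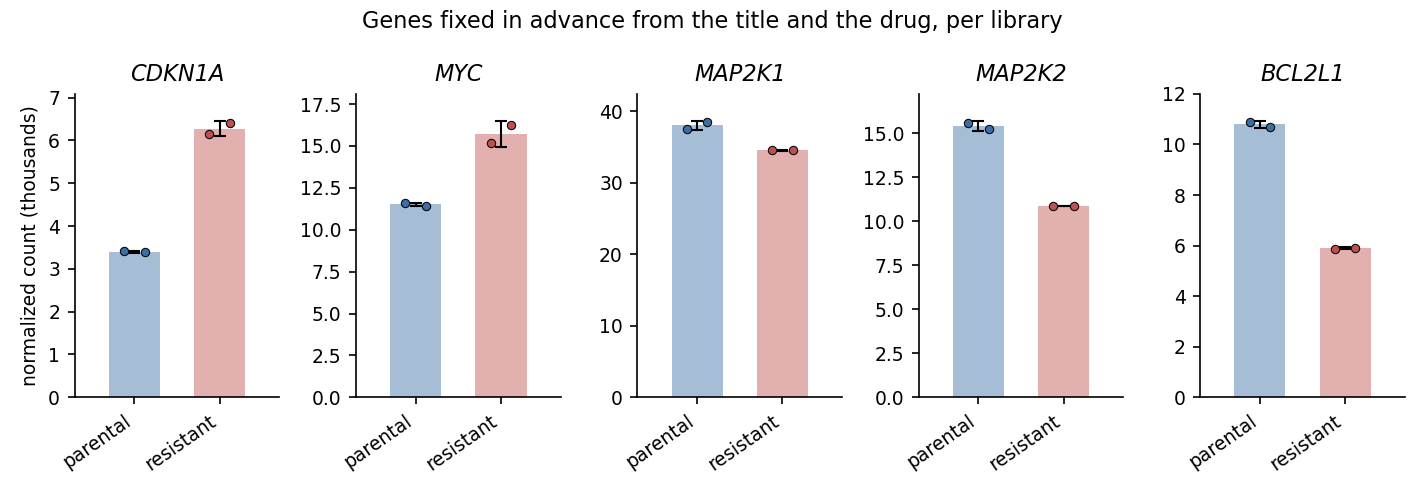
Normalized counts of CDKN1A, MYC, MAP2K1, MAP2K2 and BCL2L1 in parental (blue) and resistant (red) cells, with one dot per library, bars at the mean of 2 libraries and error bars of 1 SD. CDKN1A and MYC were higher in both resistant libraries, and MAP2K1, MAP2K2 and BCL2L1 were lower in both.

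In the GRCh38 assembly these protein-coding genes lie on chromosome 6 from 36676460 to 36687339 (CDKN1A, ENSG00000124762), chromosome 8 from 127735434 to 127741434 (MYC, ENSG00000136997), chromosome 20 from 31664452 to 31723989 (BCL2L1, ENSG00000171552), chromosome 15 from 66386817 to 66492312 (MAP2K1, ENSG00000169032) and chromosome 19 from 4090321 to 4124129 (MAP2K2, ENSG00000126934). An antisense transcript, ABALON, covers 42.8% of the exonic bases of BCL2L1, and no strand setting was stated for the counting, so reads of the pair cannot be told apart.

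Across the transcriptome, the comparison asked which genes differed between resistant and parental cells. Of 18330 genes tested with limma, 6001 were higher and 6270 lower in resistant cells at an adjusted p below 0.05, together 66.9% of the genes. A change of at least 2-fold was found for 1642 higher and 1205 lower genes, and a change of at least 4-fold for 621 higher and 314 lower genes. Among the called genes, 2983 differed by less than 1.2-fold. When a change above 1.2-fold was required, 3380 higher and 3414 lower genes passed limma's treat test, a setting chosen after seeing the data. The authors' deposited table calls 4966 genes higher and 5435 lower at an adjusted p below 0.05, and 10400 of these 10401 genes were also called here with the same sign.

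The largest increase was that of DCX, which encodes the microtubule-binding protein doublecortin of migrating neurons. It had 527 ± 29.4 normalized counts in resistant cells and 2.49 ± 3.51 in parental cells, which is 5 reads over both parental libraries, a ratio of 214 with an exact 95% counting interval of 91.6 to 662. CXCR4, a chemokine receptor of migrating cells, rose from 98.3 ± 29.7 to 6493 ± 184, a log2 fold change of 6.06 (SE 0.11), and the contactin gene CNTN6, a neuronal adhesion molecule, by 5.52 (SE 0.41). CNTN6 had 7 parental reads, and its ratio was 49.2 with a counting interval of 23.6 to 123. AFAP1L2 rose by 5.84 (SE 0.15), BAALC by 5.39 (SE 0.23), MOB3B by 5.34 (SE 0.25), RGS7, a regulator of G protein signalling, by 5.32 (SE 0.16), and the homeobox gene BARX2 by 5.24 (SE 0.15). PDZRN4 (6.21, SE 0.50), the pseudogene E2F6P4 (5.32, SE 0.30) and the long noncoding RNA LINC01139 (5.11, SE 0.21) complete the group, and the value of E2F6P4 is uncertain because its sequence resembles that of its parent gene. With 5 parental reads, PDZRN4 had a ratio of 73.7 and a counting interval of 31.3 to 228. SERTM2 had 2 parental reads, and its ratio was 146 with a counting interval of 40.0 to 1211. DCX (from 111293779 to 111412429) and SERTM2 (from 111511662 to 111522399) are neighbours on the X chromosome.

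The largest decrease was that of MKX, which encodes the tendon transcription factor mohawk. It had 9.36 ± 5.13 normalized counts in resistant cells against 1381 ± 39.7 in parental cells, a log2 fold change of -7.15 (SE 0.21). The protocadherin gene PCDH10 had a log2 fold change of -6.18 (SE 0.12), and CNTNAP2, a neuronal adhesion gene, one of -5.76 (SE 0.21). MAP7D2, which encodes a microtubule-associated protein, was lower by a log2 fold change of -6.27 (SE 0.13), ADAMTS3, a procollagen-processing protease gene, by -6.00 (SE 0.14), BMPR1B, a bone morphogenetic protein receptor gene, by -5.73 (SE 0.26), and the methionine sulfoxide reductase gene MSRB2 by -6.51 (SE 0.28). IL1B, the gene of the inflammatory cytokine interleukin-1 beta, fell from 256 ± 3.66 to 4.01 ± 1.08, a log2 fold change of -5.70 (SE 0.27). ZNF883 (-5.82, SE 0.28), BTBD17 (-5.74, SE 0.32) and FRG2 (-5.76, SE 0.29) were in the same range, with FRG2 uncertain because near-identical copies exist on other chromosomes. MILR1 had 2 reads in resistant cells, and its parental level was 111 times higher with a counting interval of 30.4 to 923. MKX lies on chromosome 10 from 27672875 to 27746060 and IL1B on chromosome 2 from 112829751 to 112836903.

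The p21 and senescence groups moved in both directions, apart from the rise of CDKN1A itself. Of 30 measured genes of the p21 axis and the DNA damage response, 12 rose, 14 fell and 4 did not pass. SERTAD1 (log2 fold change -1.14, SE 0.05), SESN2 (-1.07, SE 0.05) and GADD45A (-0.78, SE 0.04), which respond to stress and DNA damage, fell while CDKN1A rose. Among 21 cell cycle inhibitors and senescence regulators, 8 rose and 10 fell, with HMGA2, a chromatin protein of embryonic and senescent cells, higher by 1.02 (SE 0.03), and HMGA1 (-0.94, SE 0.03) and ID1 (-0.97, SE 0.04) lower. Of 42 genes of the senescence-associated secretory phenotype, 17 rose and 23 fell, with a median of -0.45. The insulin-like growth factor binding protein genes IGFBP5 (3.44, SE 0.04) and IGFBP2 (1.90, SE 0.03) rose, and the protease inhibitor genes SERPINE2 (-2.30, SE 0.03) and TIMP2 (-1.67, SE 0.03) fell, as did IL1B. The interleukin genes CXCL8 (-3.37, SE 0.08) and IL6 (-1.09, SE 0.12), named after their values were seen, also fell. Camera, which tests for a shared shift up or down, called none of these groups. Its adjusted p was 0.890 for the p21 axis and damage response, 0.838 for inhibitors and regulators, and 0.359 for secretory genes. Movement of members in both directions is not covered by that test.

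Targets of MYC and of the MEK and ERK kinases likewise split. Of 39 MYC target genes, 17 rose, 15 fell and 7 did not pass. NOLC1 and UTP20, which act in ribosome synthesis, rose by 0.58 (SE 0.03) and 0.66 (SE 0.03), CDK4 by 0.55 (SE 0.03), and lactate dehydrogenase LDHA was lower, at -0.49 (SE 0.03). CDK4 shares 51.9% of its exonic bases with TSPAN31 on the opposite strand, so its value is uncertain. Of 26 genes that report MEK and ERK output, 11 rose and 13 fell. The immediate early genes FOS (2.61, SE 0.06) and EGR1 (1.98, SE 0.04) rose, while DUSP4, a phosphatase that dampens the pathway, fell from 39253 ± 297 to 7568 ± 54.3 (-2.37, SE 0.03), and FOSL1 fell as well (-1.81, SE 0.04). Among 33 components of the RAS to ERK pathway, 9 rose and 18 fell. The adaptor gene GRB2 (-1.55, SE 0.03), HRAS (-1.05, SE 0.04) and the receptor gene EGFR (-0.87, SE 0.03) were lower, and the receptor gene FGFR4 was higher (0.72, SE 0.03). Camera called none of these lists (adjusted p = 0.593 for MYC targets, 0.680 for MEK and ERK output, and 0.233 for the components).

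In the BCL2 family, no anti-apoptotic member was called higher. Of 5 measured, BCL2L1, BCL2 (-1.08, SE 0.08) and MCL1 (-0.18, SE 0.03) fell, and 2, BCL2L2 (-0.03, SE 0.05) and BCL2L12 (-0.04, SE 0.04), both named after their values were seen, did not pass. With the shift of chromosomal neighbours removed, the values were -0.21 for BCL2L2 and 0.27 for BCL2L12. Both passed there, with p-values that take the neighbour median as known. Of 14 pro-apoptotic genes, 7 rose and 6 fell, with BMF (0.74, SE 0.05) and BNIP3 (0.47, SE 0.04) higher and BOK (-1.03, SE 0.04) and BAX (-0.48, SE 0.04) lower. Camera called neither list (adjusted p = 0.123 for anti-apoptotic and 0.838 for pro-apoptotic genes). MCL1 no longer passed when a change above 1.2-fold was required or with the dispersion fixed at 0.01 (edgeR adjusted p = 0.348).

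Drug transport and the drug target gave no uniform change. Among 12 efflux transporter genes, 3 rose, 5 fell and 4 did not pass. ABCC5 was higher (0.66, SE 0.04), and ABCC4 (-1.47, SE 0.04) and the vault protein gene MVP (-0.74, SE 0.03) were lower. ABCC1, which encodes the vincristine exporter MRP1 and was named after its value was seen, had 4544 ± 95.9 against 4598 ± 107 normalized counts (-0.02, SE 0.04) and did not pass. With the shift of its chromosomal neighbours removed its value was -0.19 (limma adjusted p = 0.000101). That p-value takes the neighbour median as known, and ABCC1 lies in no shifted chromosomal region, so a lower level is not shown. Of 17 genes that flank ABCB1 at 7q21, 7 rose, 3 fell and 7 did not pass, with STEAP2 (2.31, SE 0.16) and STEAP1 (1.42, SE 0.09) higher and SEMA3D (-1.33, SE 0.03) and CDK14 (-0.50, SE 0.04) lower. Of 14 tubulin genes, 4 rose and 5 fell. The brain and muscle isotypes TUBB2A (-1.47, SE 0.05) and TUBB2B (-0.93, SE 0.04) were lower, as was TUBA1A (-0.52, SE 0.03), and TUBA4A was higher (0.52, SE 0.03). Tubulin genes have close paralogs, so reads may have been split between them, and STK16 covers 23.4% of the exonic bases of TUBA4A from the opposite strand. Of 31 microtubule-binding protein genes, 11 rose and 12 fell, with the mitotic kinesin KIF11 (1.12, SE 0.03) and MAP2 (0.96, SE 0.03) higher beside DCX, and MAP1B (-0.92, SE 0.03) and the transport kinesin KIF5B (-0.77, SE 0.03) lower. Camera called none of the 4 lists (adjusted p = 0.632, 0.685, 0.838 and 0.890, in the order given). Median and mean differed in sign for efflux transporters (0.03 and -0.05) and for microtubule-binding proteins (-0.03 and 0.22), and the test pointed down for both.

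Proliferation genes rose together. Of 38 mitosis and spindle checkpoint genes, 32 rose, 4 fell and 2 did not pass (median log2 fold change 0.47). TOP2A, the DNA topoisomerase of dividing cells, rose from 14404 ± 84.3 to 43686 ± 1744 (1.60, SE 0.03), MKI67, the gene of the Ki-67 antigen, rose from 15687 ± 87.3 to 39599 ± 362 (1.34, SE 0.03), and the checkpoint gene BUB3 rose by 1.16 (SE 0.03). The 4 that fell were BIRC5 (-0.98, SE 0.03), the gene of survivin, and CDC25B, UBE2C and AURKA, the latter 3 named after their values were seen. Of 39 DNA replication genes, 33 rose and 5 fell (median 0.36). The origin licensing gene CDC6 (1.26, SE 0.04), the polymerase gene POLE (0.93, SE 0.03) and the transcription factor gene E2F2 (1.42, SE 0.05) rose. Those that fell, named after their values were seen, were TK1 (-0.79, SE 0.03), MCM10, CCNE1, GINS3 and CCNE2. CCNE2 lost its call without parental replicate 1 (limma adjusted p = 0.107) and without resistant replicate 2 (limma adjusted p = 0.0683), and under DESeq2 (DESeq2 adjusted p = 0.0547). UBE2C, AURKA, GINS3 and CCNE2 did not pass against 1.2-fold or with the dispersion fixed at 0.01. Camera placed both lists above the other genes (adjusted p = 7.64e-08 for mitosis and 1.13e-07 for replication). With an estimated correlation between genes in place of the preset 0.01, both calls were lost (adjusted p = 0.421 for each with an estimated correlation). None of the 28 lists passed in that setting, so a loss there does not set one list apart from another. Once the shift of chromosomal neighbours was removed, BIRC5 was higher, at 0.23, as were CDC25B (0.26), TK1 (0.42), MCM10 (0.47) and CCNE2 (0.19), and UBE2C and CCNE1 no longer passed.

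Skeletal muscle genes were higher in resistant cells. Of 41 measured genes of muscle differentiation, 32 rose, 5 fell and 4 did not pass (median 0.59). PAX7, the transcription factor of muscle satellite cells, rose from 377 ± 3.28 to 4540 ± 119 (3.58, SE 0.05), cardiac actin ACTC1 rose by 1.49 (SE 0.03), and desmin, DES, rose from 18250 ± 4.91 to 50278 ± 1256 (1.46, SE 0.03). The sarcoglycan gene SGCA fell (-1.99, SE 0.05), and the others that fell, TNNC2, TNNC1, NEB and CKB, were named after their values were seen. MYOG, the regulator of terminal differentiation, rose by 0.70 (SE 0.03), and MYOD1, its upstream regulator, had 15949 ± 1041 against 16588 ± 491 normalized counts and did not pass, both named after their values were seen. The log2 fold change of MYOD1 was -0.12 without resistant replicate 2 and 0.01 without resistant replicate 1, each with 1 resistant library. After the GC and length correction MYOD1 passed as higher (0.08, limma adjusted p = 0.0375). TNNC1 lost its call without parental replicate 1 (limma adjusted p = 0.0662), parental replicate 2 (limma adjusted p = 0.226) or resistant replicate 1 (limma adjusted p = 0.196), and under DESeq2 (DESeq2 adjusted p = 0.204), limma-voom, scaling to the same total and exclusion of the 20 most abundant genes. TNNC1, NEB and CKB did not pass against 1.2-fold or with the dispersion fixed at 0.01. The list was called by camera (adjusted p = 2.93e-07), and the call was lost with an estimated correlation (adjusted p = 0.593).

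Of 42 measured interferon-stimulated genes, 34 rose, 3 fell and 5 did not pass (median 0.69). The antiviral gene IFIT1 rose from 5494 ± 179 to 15149 ± 303 (1.46, SE 0.03), PARP9 by 1.06 (SE 0.04) and IFI6 by 1.04 (SE 0.04). IFITM2 fell (-1.08, SE 0.03), as did IFITM3 and ISG20, the latter pair named after their values were seen. IFITM3 was higher (0.35) with the shift of chromosomal neighbours removed, and it did not pass against 1.2-fold or with the dispersion fixed at 0.01, while ISG20 did not pass against 1.2-fold. Of 17 antigen presentation genes, 13 rose and TAP1 alone, named after its value was seen, fell, a call lost against 1.2-fold and with the dispersion fixed at 0.01. The immunoproteasome genes PSMB8 (0.84, SE 0.05) and PSMB9 (0.90, SE 0.06), HLA-B (0.66, SE 0.05) and beta-2-microglobulin, B2M (0.41, SE 0.03), rose, with HLA values uncertain because the HLA genes are near-identical in part and an antisense gene covers 23.5% of the exonic bases of HLA-B. Camera called both lists (adjusted p = 4.76e-09 for interferon-stimulated and 0.00359 for antigen presentation genes), and both calls were lost with an estimated correlation (adjusted p = 0.421 for each). The antigen presentation call was also lost without resistant replicate 2, with a median of 0.37 in both fits. With the shift of chromosomal neighbours removed it was lost as well (camera adjusted p = 0.0696). The median there was 0.29 (quartiles 0.11 and 0.51) against 0.37 (quartiles 0.21 and 0.84). Members such as PSMB8 and PSMB9 lie side by side on chromosome 6, so that removal takes away part of the list's own rise. The list has 0 members in the shifted chromosomal regions.

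Stress response genes were lower. Of 33 genes of the integrated stress and unfolded protein responses, 26 fell, 4 rose and 3 did not pass (median -0.37). PPP1R15A, which restores translation after stress, fell from 9498 ± 6.18 to 3787 ± 29.2 (-1.33, SE 0.03), the kinase-like gene TRIB3 fell by a log2 fold change of -1.53 (SE 0.06), the chaperone gene DNAJC3 by -1.01 (SE 0.04) and the amino acid transporter SLC7A5 by -0.76 (SE 0.03). The 4 that rose, named after their values were seen, were SHMT2, DDIT4, PSAT1 and HSP90B1, of which HSP90B1 lost its call without parental replicate 1 (limma adjusted p = 0.0506). With the shift of chromosomal neighbours removed, HSP90B1 was lower (-0.37) and DDIT4 no longer passed (limma adjusted p = 0.467). PSAT1 and HSP90B1 did not pass against 1.2-fold or with the dispersion fixed at 0.01. Camera called the list lower (adjusted p = 9.37e-06), and the call was lost with an estimated correlation (adjusted p = 0.421).

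Translation and mitochondrial genes rose by smaller amounts. Of 32 cytoplasmic ribosomal protein genes, 22 rose and 7 fell (median 0.22), with RPL19 (0.58, SE 0.03), RPL10A (0.57, SE 0.03), RPLP0 (0.56, SE 0.03) and RPL37A (0.53, SE 0.03) among those that rose. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. Of 13 mitochondrially encoded genes, 11 rose and MT-ND3 alone, named after its value was seen, fell, a call lost against 1.2-fold and with the dispersion fixed at 0.01 (median of the list 0.18), with MT-ND1 (0.44, SE 0.03) and MT-ND4 (0.43, SE 0.03) the clearest. Camera called both lists (adjusted p = 0.000739 for ribosomal and 0.00449 for mitochondrial genes), and both calls were lost with an estimated correlation (adjusted p = 0.850 and 0.763). The mitochondrial call was also lost without parental replicate 1 (median 0.17) and without parental replicate 2 (median 0.19), each a fit with 1 parental library. After a correction for GC content and transcript length it was lost too (camera adjusted p = 0.0662). The median there was 0.15 (quartiles 0.10 and 0.22) against 0.18 (quartiles 0.13 and 0.26) in the main fit.

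**Figure D2:**
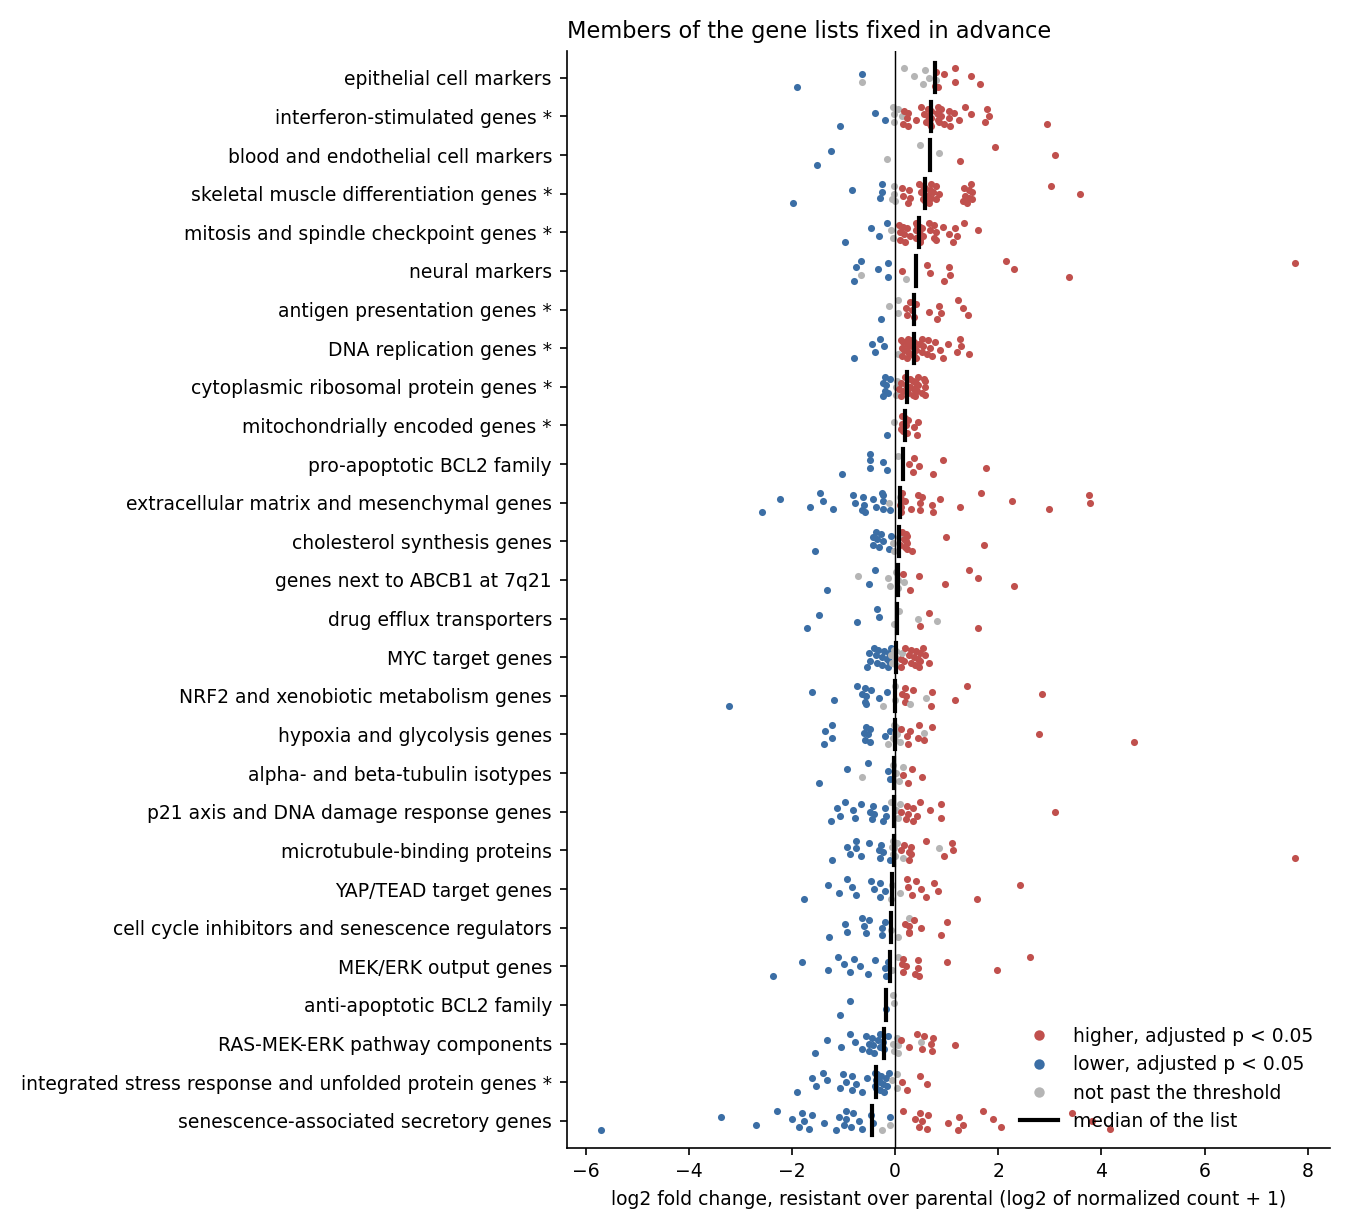
Log2 fold change, resistant over parental, of every measured member of the 28 gene lists fixed in advance (one dot per gene, colour by limma result, black bars at the list medians). Lists with an asterisk passed camera with the preset correlation of 0.01, among them interferon-stimulated genes (median 0.69) above and stress response genes (median -0.37) below the other genes.

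Of 41 matrix and mesenchymal genes, 20 rose and 19 fell. The collagen gene COL6A3 rose from 3912 ± 100 to 53885 ± 403 (3.78, SE 0.03) and the fibrillin gene FBN2 by 3.77 (SE 0.04), while COL12A1 (-2.22, SE 0.03) and the thrombospondin gene THBS1 (-2.58, SE 0.04) fell. Median and mean of this list were 0.09 and 0.11, and the test pointed down (camera adjusted p = 0.890). Of 24 target genes of the YAP and TEAD regulators, 10 rose and 11 fell, and the receptor gene AXL (-1.76, SE 0.03), NT5E (-1.09, SE 0.03), PTPN14 (-1.30, SE 0.04) and CRIM1 (-0.93, SE 0.03) were lower (camera adjusted p = 0.685). Of 25 cholesterol synthesis genes, 12 rose and 10 fell, with STARD4 higher (0.99, SE 0.05) and TM7SF2 (-1.55, SE 0.07) and LSS (-0.43, SE 0.03) lower (camera adjusted p = 0.890). ACAT2 was lower too (-0.43, SE 0.03), but antisense genes cover part of its exons. Of 31 hypoxia and glycolysis genes, 10 rose and 12 fell. The oxygen sensor gene EGLN3 rose from 39.1 ± 10.3 to 972 ± 15.1 (4.62, SE 0.14), and PFKP (-1.36, SE 0.03), the lactate exporter SLC16A3 (-1.22, SE 0.04) and VEGFA (-1.37, SE 0.05) fell, with a median of -0.01 and a mean of 0.07 and a test that pointed down (camera adjusted p = 0.685). Of 27 NRF2 and xenobiotic metabolism genes, 10 rose and 12 fell, with MGST1 higher (1.16, SE 0.05) and NQO1 (-0.73, SE 0.03), SLC7A11 (-1.61, SE 0.08) and PGD (-0.57, SE 0.03) lower (camera adjusted p = 0.593).

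Markers of other cell types were measured as a check of the cultures. Of 17 epithelial markers, 8 rose and 2 fell, and the most abundant, the keratin gene KRT18, rose from 4427 ± 27.1 to 13883 ± 193 (1.65, SE 0.03). KRT8 rose from 283 ± 9.67 to 790 ± 15.5, and KRT7 fell from 208 ± 19.3 to 56.1 ± 15.1. Of 8 blood and endothelial markers, 3 rose and 2 fell, and the most abundant, the endothelial receptor gene TEK, rose from 199 ± 15.7 to 1710 ± 27.4 (3.10, SE 0.08). TIE1 was higher (1.94, SE 0.12) and CLDN5 lower (-1.24, SE 0.09), and CD68 (-1.52, SE 0.42) is uncertain because a read-through gene covers 95.3% of its exonic bases. Of 18 neural markers, 10 rose and 6 fell. The most abundant, NES, which muscle precursors also express, was at 92149 ± 382 against 84172 ± 1061 (0.13, SE 0.03), and lost its call without parental replicate 2 (limma adjusted p = 0.0515), against 1.2-fold and with the dispersion fixed at 0.01 (edgeR adjusted p = 0.487). The neurofilament genes NEFH (3.37, SE 0.06) and NEFM (2.30, SE 0.03) rose, with NEFM sharing 38.9% of its exonic bases with an antisense gene, and L1CAM fell (-0.77, SE 0.03). Camera called none of the 3 lists in the main fit (adjusted p = 0.267 for epithelial, 0.593 for blood and endothelial, and 0.103 for neural markers). Neural markers passed when any 1 library was left out, but such a fit has 1 library in a group. Its p-value lacks the spread of that group, so no call is drawn from it. With the replicate number as a block, which keeps all libraries, neural markers passed too (camera adjusted p = 0.000694). The replicate numbers do not pair the libraries, so whether neural markers moved as a group stays open.

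Many of the named genes lie in chromosomal regions whose genes moved in the same direction. Of 17727 genes with a position, 4231 (23.9%) lay in 19 regions of at least 30 genes with a median log2 fold change of at least 0.25 in size, 7 higher and 12 lower. On chromosome 17, 221 genes between 60.1 and 81.0 Mb had a median of -1.23, and these include GRB2, TIMP2 and BIRC5, while 63 genes between 39.1 and 42.4 Mb, TOP2A, CDC6 and RPL19 among them, had a median of 0.82. On chromosome 10, 153 genes between 0.134 and 38.4 Mb, including MKX, MSRB2, KIF5B and PFKP, had a median of -0.79, and 553 genes from 42.3 to 133.6 Mb, including MKI67, BUB3, KIF11, IFIT1 and NOLC1, had a median of 0.56. ABCC4 and DNAJC3 lay in a region of chromosome 13 with a median of -0.81, and TUBB2A and TUBB2B in a region of chromosome 6 with a median of -0.72. Some named genes moved against their region. SERPINE2 (-2.30) and BOK (-1.03) lay among 482 genes of chromosome 2 with a median of 0.25. BAALC (5.39) lay in a region of chromosome 8 with a median of -0.40. With the median of the 20 nearest neighbours removed, a setting chosen after seeing the data, KIF5B had a log2 fold change of 0.04, and BAX and BNIP3 no longer passed (limma adjusted p = 0.0566 and 0.141). These regions hold 27.3% of the called genes that have a position, and 34.2% of those called with a change of at least 2-fold.

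**Figure D3:**
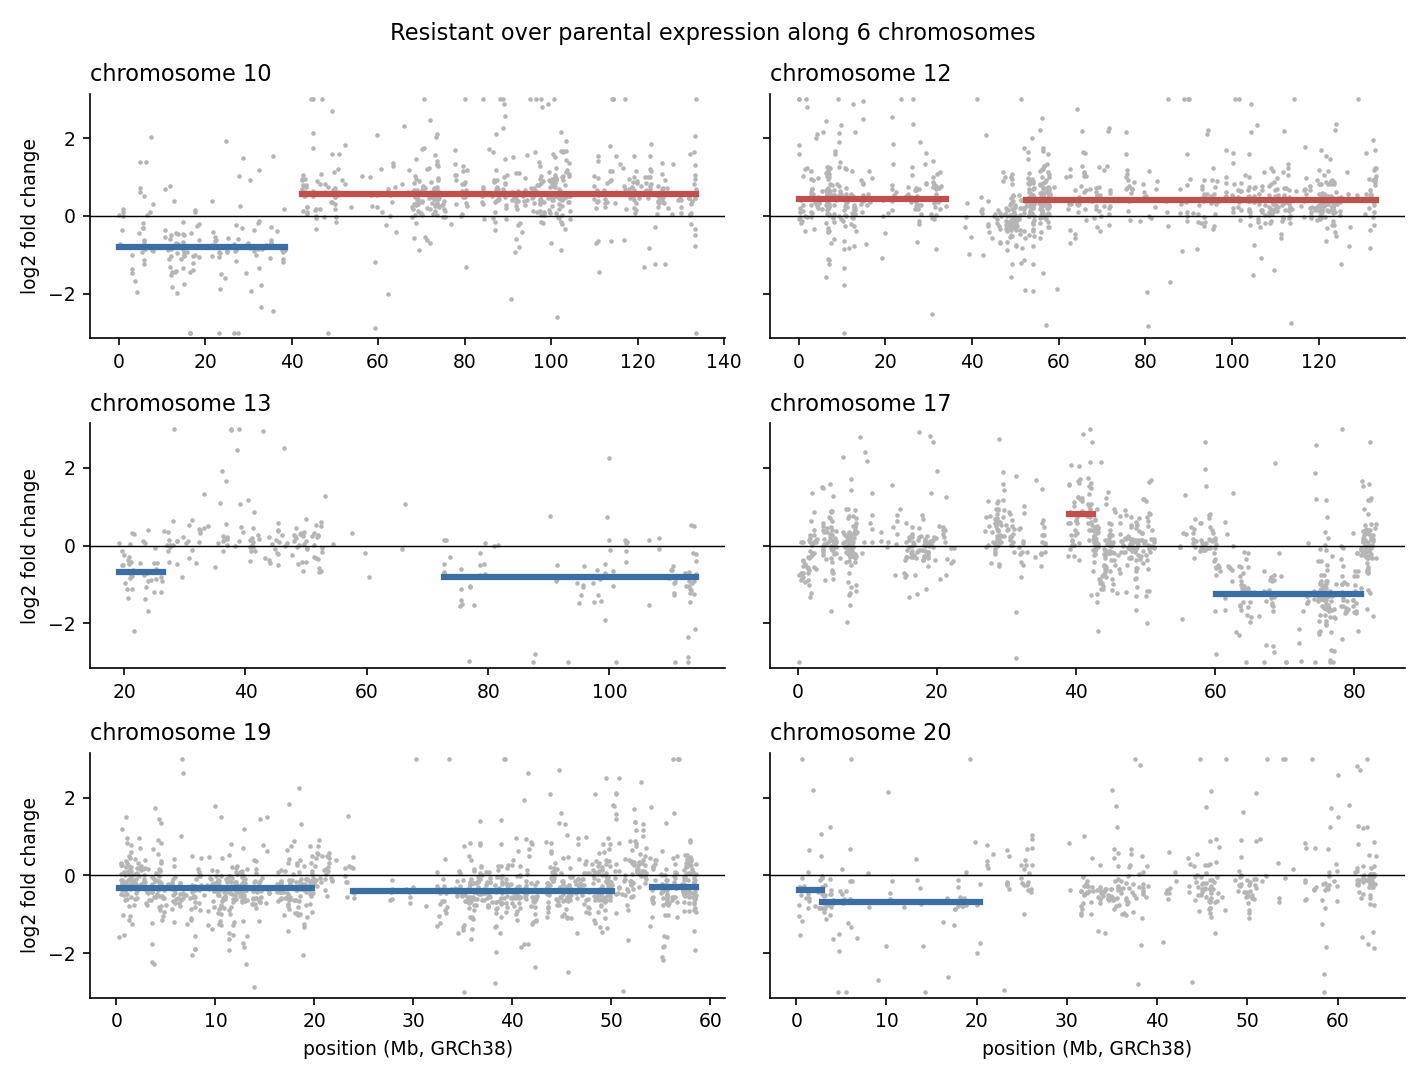
Log2 fold change, resistant over parental, of each tested gene (grey) by its start position in Mb on 6 chromosomes, with values beyond 3 in size drawn at 3, and a line at the median of each region found by segmentation (red for higher, blue for lower). Chromosome 10 changes sign near the centromere (-0.79 to 0.56), and a block of chromosome 17 lies at -1.23.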

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

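The treat test against 1.2-fold, the fixed dispersion, the GC and length correction, the removal of regional shifts and the exclusion of shifted regions were tests chosen after the data were seen. The counts of higher and lower genes stayed within 1.5 times of 6001 and 6270 under every alternative fixed in advance, with totals of 10401 (DESeq2) to 12367 (edgeR) calls, and leaving out one library gave totals of 10786 to 12192. The share of calls that were higher ranged from 47.2% to 52.9% over those settings. Quantile normalization moved the genes changed by at least 2-fold to 1404 higher and 1417 lower, a higher share of 49.8% against 57.7%, so their lean toward increases depends on the normalization. Tested against 1.2-fold, 3380 genes were higher and 3414 lower, fewer because small changes are excluded by construction. With the dispersion fixed at 0.01, 3880 genes were lower and 4062 higher, fewer because a wider spread is assumed. A filter of 50 left 1092 genes higher by at least 2-fold, with 14730 genes tested, and without the genes in shifted regions 740 were lower by at least 2-fold, with 14099 tested. The authors' deposited table has 10401 calls, and 2561 with a change of at least 2-fold. Of the 28 lists, 8 were called by camera, 0 with an estimated correlation and 24 by fry, which does not compare a list with other genes, and the cause of the loss was not tested. Fry gave cholesterol synthesis genes the opposite direction to camera, with a median of 0.0667. With the shift of neighbours removed, KIF5B turned to 0.0393 and BIRC5 to 0.23, and of the other 136 genes of the naming rule 134 kept their direction and call. Among the genes named outside the rule, CDC25B, TK1, MCM10, CCNE2, IFITM3, HSP90B1 and BCL2L12 changed sign there and passed, and UBE2C, CCNE1 and MYOD1 changed sign without passing. Same-numbered libraries did not deviate together (r = -0.0296 across genes), so the numbers do not pair them. With the replicate block 5926 genes were higher and 6218 lower, and 1638 higher and 1207 lower by at least 2-fold, with 7 lists called, antigen presentation (0.0602) and mitochondrial genes (0.18) not among them and neural markers (0.000694) added. The largest running median moved with the window, to 3.11 around SERTM2 on the X chromosome with 11 genes and -1.52 around UBALD2 on chromosome 17 with 41 genes, a size of 1.52. Depth limits genes with few reads, such as DCX with 5 parental reads, for which the size of the fold stays wide.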

Other observations

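Tests chosen only after the result was seen were the regional segments, the tests on genes left out of the segmentation, the muscle list as a lineage check, the correction for GC content and length, the removal of the shift of neighbours, the exclusion of shifted regions, the restriction to lists with members there and the fixed coefficient of variation. Expression along the chromosomes differed between resistant and parental cells in long stretches. The largest running median over 21 genes was 1.76, at the HOXD cluster on chromosome 2 around HOXD-AS2, against a highest value of 1.12 in 1000 shuffles of gene order (permutation p = 0.001, the smallest they can give). Beside the regions of chromosomes 10 and 17, most of chromosome 12 was higher, with medians of 0.45 for 258 genes up to 34.0 Mb and 0.40 for 592 genes from 52.4 Mb, which include HMGA2, CDK4, RPLP0 and KRT18. On chromosome 13, 42 genes between 19.2 and 26.4 Mb had a median of -0.67 and 103 genes from 72.7 Mb to the end had a median of -0.81, and on chromosome 20, 85 genes between 2.84 and 20.4 Mb had a median of -0.70. Chromosome 19 was lower over 3 regions, with medians of -0.32, -0.39 and -0.30 for 510, 457 and 158 genes, among them MAP2K2, AXL and BAX. The medians of the resistant libraries, each taken against the parental mean, differed by at most 0.0918 in any region.

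Neighbouring genes moved together in these regions, and a gene dosage difference between resistant and parental cells is a candidate explanation. When 17 regions were found on every other gene, the weakly, middle and strongly expressed genes left out all had medians of the region's sign in 70.6% of them (12), between the bounds set for either answer, so dosage and other regional causes cannot be told apart, and the same test on the genes that defined the regions (17 of 19) was set aside because their choice favours it. The tables argue against GC content and transcript length, since 94.7% of the 19 regions kept their sign and a median of at least 0.25 in size after correction, and against a few strongly changed genes, since a median of 76.4% of the genes left out moved with their region, with a smallest share of 61.5%, although 4 of the 17 regions fell below a median of 0.25 in size among these genes. The muscle list had a median of 0.59, which argues against a culture of a non-muscle lineage in place of RD cells. This check was set after that value was known. It cannot address another line of the muscle lineage or a mixture of cells, so the identity of the cultures stays open. DNA copy number was not analysed here, and regional chromatin changes or selection of a subclone of the parental line, which may not depend on vincristine, stay open.

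Camera with the preset correlation called 8 of the 28 lists, and positions in shifted regions could have contributed, since the share of members there ranged from 0% for antigen presentation and mitochondrially encoded genes to 40.6% for ribosomal protein genes, against 23.9% of all genes with a position. The 6 called lists with members in shifted regions all kept their camera call with the shift of neighbours removed and without the genes in these regions, which argues against position in them as the whole cause for those 6, while over the 7 lists with a neighbour value 6 kept it, short of an earlier bound of 7. After the GC and length correction 7 of the 8 kept it, which equals the bound set before that test with no margin and argues against this bias for those lists. Mitochondrially encoded genes lost the call (camera adjusted p = 0.0662) while their median stayed at 0.15 against 0.18, so for them GC and length cannot be told apart from a change in the cells. With an estimated correlation between genes 0 of the 8 calls were kept, and the smallest camera adjusted p of the 28 lists was 0.421. A higher correlation does not explain every loss, since antigen presentation genes had an estimate of -0.0561, below the preset 0.01. DNA replication genes had an estimate of 0.0187, close to the preset, and went from a camera adjusted p of 1.13e-07 to 0.421. What else ended the calls was not tested, and 4 libraries may be too few for this setting to call any list. The loss of the calls there is therefore no evidence for or against a change of the lists. The change of the lists as groups stays open.

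About 67% of the genes passed the test, and replicate libraries that do not sample the spread between cultures may account for part of these calls. With a coefficient of variation of 10% set in place of the measured 2.38%, 64.3% of the calls remained with the same sign. This lies between the bounds set for either answer before that test was run, so real differences between the cells and a too narrow replicate spread cannot be told apart. The 10% is an assumed spread and no estimate of the spread between cultures, so the calls that remained are not settled by it either. The labels name no separate cultures, which keeps the question open.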
